A study of Arabidopsis thaliana with 18 samples.

How the data were processed

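Developing seeds of Arabidopsis thaliana were collected at 9 to 10 days after flowering from wild type (Col-0) and from a double knockout of BADC1 and BADC3, and polyA RNA was sequenced. The 18 samples fall into 6 groups of 3. The first set holds the groups titled COL0 and badc-tdna13. The second set holds AtWT and AtBD, and AtWTtr and AtBDtr, whose titles add "tr". Per the labels, the study also isolated ribosome-associated RNA with a FLAG-tagged RPL18 transgene under a soybean glycinin promoter, but no label spells out what "tr" stands for, so these libraries are called tr libraries here.

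For all samples the labels name TopHat, Cufflinks, Cuffdiff and the TAIR10 build, without versions. For the first set the authors deposited a Cuffdiff table with 1 entry per locus, condition and replicate. Its fragments are deposited as unscaled expected counts (non-integer estimates) per locus, and 1633 of the 199206 values are not whole numbers. Its second unit, per the file headers, is FPKM, scaled by Cuffdiff. Its replicates carry the numbers 0, 1 and 2 and the sample titles carry letters, so the libraries are named by condition and number ("Col-0 replicate 0", "tDNA replicate 0"). Loci of the first set were given identifiers from the deposited symbol and identifier columns where these did not conflict and where the identifier lay in the same stretch of the genome as its neighbours. Of 33201 loci, 30144 received 1 identifier, and 82 identifiers of another stretch were not used. Only 24 of 206 cytosolic ribosomal protein genes could be tested in the first set under this matching.

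For the second set the authors deposited raw counts per gene for 33602 loci, together with per-library count files in the layout of STAR's gene counts, a counter that the labels do not mention. The deposited count table equals the unstranded column of those files in all 12 libraries. The stranded columns split evenly (49.9% to 50.7% on 1 strand) although the kit is labelled stranded, so the unstranded counts were used, and reads of overlapping or antisense genes cannot be told apart.

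Counts (fragments rounded in the first set) were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr, libraries were scaled with TMM, and the quasi-likelihood test was applied with a Benjamini-Hochberg adjusted p under 0.05 and no fold minimum. The 6 libraries of the first set were fitted alone. The 12 libraries of the second set were fitted together with 1 coefficient per group, which gave the genotype contrasts, the contrasts of tr with the other libraries and their interaction. Values per gene are CPM, counts scaled by the TMM-adjusted library total, as mean and SD over the 3 libraries of a group, and fold changes are log2 with their standard error (SE). A gene with no count in any library of a group was compared with a floor of 3 counts over the group.

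Before the data were examined, 22 gene lists, the rule for named genes, the tests and most alternatives were fixed. The lists were the heteromeric acetyl-CoA carboxylase with BADC, plastid fatty acid synthesis and export, triacylglycerol assembly, oil body proteins, lipolysis with beta-oxidation and the glyoxylate cycle, storage proteins, seed maturation regulators, late maturation and desiccation, sucrose breakdown with glycolysis, starch metabolism, nuclear photosynthesis genes, other biotin enzymes, ER protein folding, hypoxia, heat shock and wounding, seed coat, endosperm, silique wall, cell division, plastid-encoded, mitochondrion-encoded and cytosolic ribosomal protein genes. The 4 members that the annotation describes as something else were left out (AT3G02900 and AT5G16660 of the carboxylase list, AT1G65090 and AT5G16550 of the oil body list). Lists were tested with camera (preset correlation 0.01, then an estimated correlation) and with fry in limma 3.58.1, adjusted over the 22 lists of a comparison. Genes were named if they belonged to the carboxylase and BADC list, if they were among the 10 largest rises or falls past the threshold with a mean log2 CPM of at least 2 and no overlap between groups, if they were among the 4 list members with the smallest adjusted p, or if they encode RPL18.

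The alternatives were RLE scaling, DESeq2 1.42.0, no filter on low counts, at least 1 CPM in every library of 1 group, nuclear genes only, log2(FPKM + 1) and log2(FPKM + 0.1) with limma-trend, counts of 1 strand, the replicate number as a block, fits of only the libraries compared, an absolute log2 fold change of at least 1, a z-score of at least 2 for the interaction, and leaving out each library in turn. Leaving out 2 identical libraries of the first set, and counts of 1 strand, were added after the data had been seen. Replicate numbers did not pair the libraries of the second set: deviations of libraries with the same number correlated above 0.1 in 0 of 3 pairs in each of 4 comparisons. The pipeline was tested on simulated data with 100 genes changed at each fold. Of the 4-fold changes it recovered 59.8% in the first set with all 6 libraries, 87% with 4 libraries, between 66.3% and 71.4% in the 4 simple contrasts of the second set and 39.8% in the interaction. Of the 2-fold changes it recovered 8.25%, 39.8%, between 14.1% and 21.6%, and 1.02%. In the simulated first set all 6 libraries were drawn separately, whereas 2 of the real ones are identical across the groups. The recoveries of 59.8% and 8.25% therefore do not apply to the real 6 libraries. Library totals ran from 9546528 to 11574156 fragments in the first set and from 16977673 to 32547007 counts in the second. The labels do not say whether replicates are separate plants, so p-values measure only the spread between these samples.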

Results

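Transcripts of developing Arabidopsis seeds were counted in a double knockout of BADC1 and BADC3 and in wild type. BADC proteins resemble the biotin carrier subunit of the plastid acetyl-CoA carboxylase, which makes malonyl-CoA for fatty acid synthesis, but carry no biotin and hold the enzyme back. The study asked what follows in metabolism when seed oil rises in this mutant. The first set held 3 libraries titled COL0 and 3 titled badc-tdna13, with totals of 9546528 to 11574156 fragments. The second set held 3 libraries each of AtWT, AtBD, AtWTtr and AtBDtr, with totals of 16977673 to 32547007 counts.

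In the second set both target genes were nearly silent in the mutant. BADC3 (AT3G15690, chromosome 3, 5316916 to 5320121 of TAIR10) had 72.5 ± 8.33 CPM in AtWT and 0.310 ± 0.337 in AtBD (SD, n = 3 each). BADC1 (AT3G56130, chromosome 3, 20826576 to 20829270) had 70.7 ± 8.09 CPM in AtWT and 1.96 ± 0.566 in AtBD. The AtBD libraries kept 0.109% to 0.962% of the wild-type mean of BADC3 and 2.28% to 3.70% of that of BADC1. In AtBDtr these shares were 0.130% to 0.542% and 2.24% to 5.30%. In the first set BADC1 is merged with its neighbour AT3G56140, 11 bases away, into 1 locus, so its residual level includes the neighbour. The libraries tDNA replicate 0 and tDNA replicate 1 kept 8.46% and 4.08% of the wild-type mean of BADC3, and 33.4% and 36.3% of that of the BADC1 locus. The library labelled tDNA replicate 2 had 79.2% and 101%. The wild-type mean of the first set includes Col-0 replicate 2, which holds the same fragments as tDNA replicate 2, as described below.

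**Figure D1:**
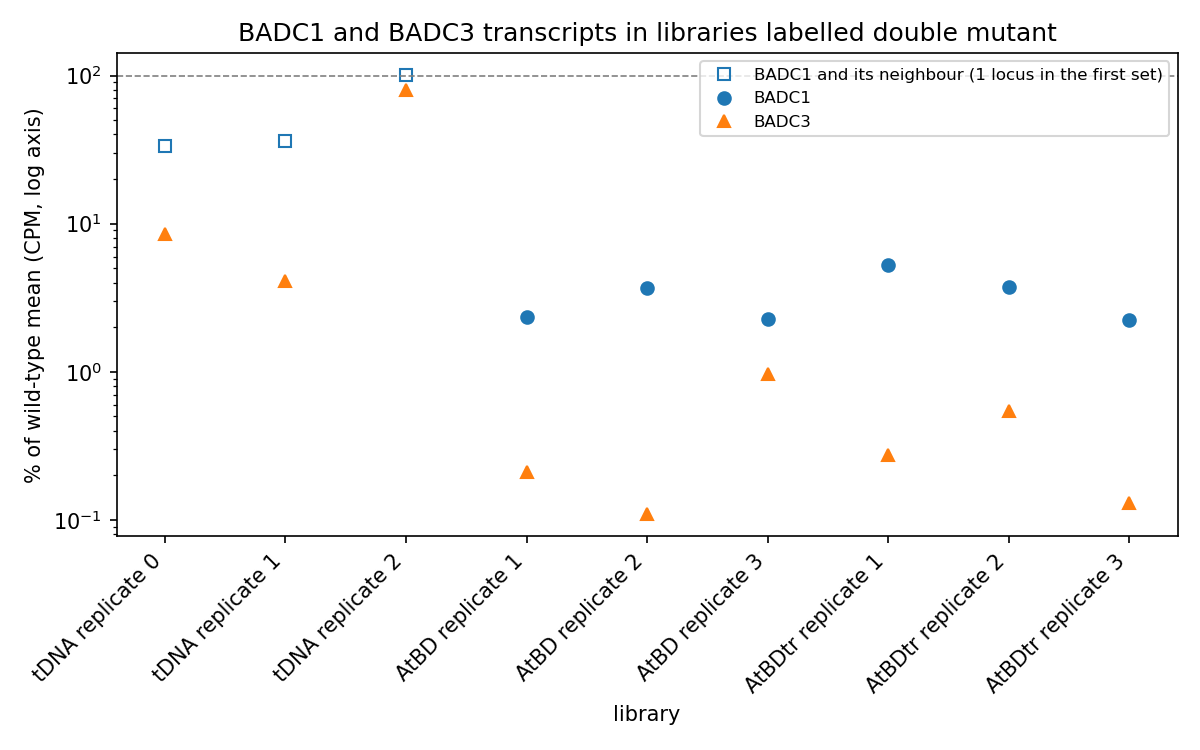
BADC1 and BADC3 in each library labelled as the double mutant, as percent of the mean of the wild-type libraries of the same set and kind (log axis, 1 point per library, dashed line at 100). The AtBD and AtBDtr libraries lie at or below 5.30%, and the library labelled tDNA replicate 2 lies at 79.2% for BADC3. The wild-type mean of the first set includes Col-0 replicate 2, whose fragments are the same as those of tDNA replicate 2.

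The first set asks how the mutant's seed transcriptome differs from wild type. With all 6 libraries, BADC3 had a log2 fold change of -1.70 (SE 0.99, adjusted p = 0.818), from 82.4 ± 14.9 CPM in COL0 to 25.2 ± 34.8 in badc-tdna13 (SD, n = 3 each). The BADC1 locus had -0.81 (SE 0.43) and the third family member, BADC2 (AT1G52670), -0.70 (SE 0.28), each with an adjusted p of 0.818. Late maturation genes had a mean log2 fold change of 1.16, with all 19 tested members positive, and plastid fatty acid synthesis genes a mean of -0.39, with 2 of 27 positive. Camera called both lists (adjusted p = 0.00028 and 2.5e-07) and 9 others, and none held with an estimated correlation (adjusted p = 0.75 for both named lists). Fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes, called 0 lists (lowest adjusted p = 0.73). No gene passed the threshold with edgeR among 18584 tested, where 974 had an unadjusted p under 0.05. DESeq2 also gave 0 (1093 unadjusted), and the FPKM fits gave 0. Identical fragments in a library of each group, described below, made the groups overlap at every gene. These counts of 0 therefore do not argue against a genotype difference.

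In this set, Col-0 replicate 2 and tDNA replicate 2 hold the same number of fragments at 17412 of 17412 loci with at least 20 fragments on average. Only loci that Cuffdiff gave the status OK in every library were compared. With loci of any status, 1 differed, and the totals were 10624146 and 10787634 fragments. Leaving both out, an alternative chosen after the data had been seen, gave 2092 genes past the threshold among 18518 (1063 higher and 1029 lower in badc-tdna13, n = 2 each). Leaving out tDNA replicate 2 alone gave 0 with edgeR among 18814 (2085 at an unadjusted p under 0.05), and so did leaving out Col-0 replicate 2 alone (4636 unadjusted). The count of 2092 rests on single libraries. It was 19 without Col-0 replicate 0, 2 without Col-0 replicate 1, 7554 without tDNA replicate 0 and 4924 without tDNA replicate 1, where the lone library of a group is assumed to vary like the other group. In the simulated data of this design, 12.6% of the genes called were unchanged ones.

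With those 4 libraries, WRI1 and part of the plastid fatty acid synthesis genes were lower in the tDNA libraries. The log2 correlation across loci was 0.985 between Col-0 replicates 0 and 1, but 0.902 between tDNA replicates 0 and 1. Between the groups it was 0.890 to 0.921, so the tDNA libraries differed from each other about as much as from Col-0. Changes of genes other than the targets with these 4 libraries may thus reflect single libraries and not the genotype. BADC3 fell by 4.16 (SE 0.31), the BADC1 locus by 1.53 (SE 0.14), BADC2 by 0.97 (SE 0.15) and the biotin carrier BCCP1 by 0.60 (SE 0.14) on the log2 scale. In the identical libraries left out, BADC2 stood at 114 CPM. BADC2 had 119 and 108 in tDNA replicates 0 and 1, and 217 and 223 in Col-0 replicates 0 and 1. BCCP1 stood at 72.5 CPM, against 62.2 and 62.0, and 87.5 and 98.6. BADC3 and the BADC1 locus were nearer to Col-0 there (65.3 and 101.7 CPM), so the falls of BADC2 and BCCP1 cannot be tied to the genotype. Of the 8 carboxylase and BADC genes tested as a list, in which the merged BADC1 locus is not counted, 3 were lower (3 adjusted over the list alone). WRI1 (AT3G54320), the transcription factor that activates glycolysis and fatty acid synthesis genes in seeds, fell from 170 ± 10.8 to 54.9 ± 9.82 CPM (SD, n = 2 each). Of 27 plastid fatty acid synthesis and export genes, 10 were lower and 0 higher (16 and 0 adjusted over the list alone), and camera's call of this list did not hold with an estimated correlation (adjusted p = 0.91). FAB2, the stearoyl-ACP desaturase, fell from 846 ± 17.7 to 423 ± 11.1 CPM, and the acyl-ACP thioesterases FATA1 and FATA2 were at -1.06 (SE 0.15) and -0.94 (SE 0.14). GPT2, which imports glucose 6-phosphate into plastids, fell from 473 ± 37.7 to 49.1 ± 10.0 CPM, but was called higher in AtBD in the fit of only the AtBD and AtWT libraries. Starch genes held 4 lower of 21 (1 higher and 7 lower adjusted over the list alone), among them the granule-bound starch synthase GBSS1 at -2.00 (SE 0.15). Of 39 nuclear photosynthesis genes 5 were lower (5 adjusted over the list alone), among them LHCB2.2 at -1.18 (SE 0.16). Every gene named in this paragraph missed the threshold without Col-0 replicate 1, and every one but GPT2 without Col-0 replicate 0. Over the alternatives, the highest adjusted p was 0.155 for BADC3, 0.174 for WRI1 and 0.476 for BCCP1.

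Part of the late maturation genes and of the genes of lipid breakdown moved the other way with these 4 libraries. Of 19 late maturation and desiccation genes 8 were higher and 0 lower (13 and 0 adjusted over the list alone), among them LEA25 (AT2G42560), from 432 ± 26.0 to 1443 ± 133 CPM, and M10 (AT2G41280) at 2.85 (SE 0.25). Of 19 genes of lipolysis, beta-oxidation and the glyoxylate cycle 8 were higher and 1 lower (10 and 1 adjusted over the list alone). Malate synthase (MLS, AT5G03860) rose from 93.1 ± 0.840 to 341 ± 1.7 CPM and isocitrate lyase (ICL, AT3G21720) from 392 ± 9.98 to 845 ± 10.2. The asparagine synthetase ASN1 (AT3G47340), a gene induced when sugar is short, rose by 3.53 (SE 0.41). The fermentation enzymes PDC1 and ADH1, of the hypoxia list (1 higher, 4 lower of 9; 1 and 5 adjusted over the list alone), were at -2.64 (SE 0.15) and -1.40 (SE 0.17). The xyloglucan endotransglucosylases XTH16, XTH9 and XTH15 were at -3.60, -3.58 and -3.20 (SE 0.15, 0.39 and 0.19). Camera called 10 lists, the named carboxylase, fatty acid synthesis, starch, photosynthesis, hypoxia, late maturation and lipolysis lists among them, and none held with an estimated correlation (adjusted p = 0.91 for each of these 7, 0.91 for cell division and ribosomal protein genes and 0.93 for plastid-encoded genes). Fry called 0 lists (lowest adjusted p = 0.13). Without Col-0 replicate 1, XTH16 alone of the genes named in this paragraph passed, and XTH15 had an adjusted p of 0.118. LEA25, M10, MLS, ICL, ADH1 and XTH9 also missed the threshold without Col-0 replicate 0, and ASN1 without tDNA replicate 0 or tDNA replicate 1 (highest adjusted p = 0.153). The remaining lists held few calls: 2 higher and 1 lower of 8 other biotin enzymes, 2 and 1 of 11 oil body proteins, 3 and 2 of 17 triacylglycerol genes, 1 and 3 of 19 maturation regulators, 2 and 2 of 22 sucrose and glycolysis genes, and 1 and 4 of 13 seed coat genes. Adjusted over the list alone these were 3 and 2, 3 and 1, 4 and 3, 2 and 5, 2 and 6, and 2 and 4.

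AtBD against AtWT asks the same question in the second set, where few genes passed the threshold. Besides BADC3 (log2 fold change -7.89, SE 0.48, adjusted p = 5.46e-07) and BADC1 (-5.17, SE 0.31, adjusted p = 2.33e-07), the named genes were 5 that rose and 2 that fell. AT1G72680, annotated as a cinnamyl-alcohol dehydrogenase, rose from 1.21 ± 0.492 to 30.2 ± 4.51 CPM (SD, n = 3 each; adjusted p = 5.46e-07). FKF1 (AT1G68050), a blue-light receptor of the photoperiod pathway, rose by 1.93 (SE 0.27), IAA32 (AT2G01200), an auxin response regulator, by 1.74 (SE 0.26), the DnaJ-domain gene AT1G56300 by 1.45 (SE 0.22) and the knottin AT2G43535 by 1.37 (SE 0.24). AT5G26220, a ChaC-like gene of the family that degrades glutathione, fell by 2.60 (SE 0.39), and AT1G28710, a sugar transferase, by 1.68 (SE 0.29). AT1G56300 and AT1G28710 missed the threshold without any 1 of the 6 libraries (highest adjusted p = 0.158 and 0.298), and AT2G43535 without any but AtWT replicate 2 (0.329). AT5G26220 missed it without any but AtWT replicate 1 (0.131), and IAA32 without AtBD replicate 3, AtWT replicate 1 or AtWT replicate 3 (0.0948). With the replicate block 2 named genes lost the call. RLE scaling, counts of 1 strand and the minimum of 1 CPM each ended the call of 1 named gene.

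Of 19376 genes tested in AtBD against AtWT, 12 passed (6 higher, 6 lower), and the groups did not overlap for 19.7% of all genes, where chance gives 10%. Outside the rule for named genes lie AT2G06950 (no count in AtWT, 18.8 ± 4.31 CPM in AtBD, at least 715-fold higher over the floor), AT5G35935 (-6.52, SE 0.78) and AT2G25510 (-4.78, SE 0.70), 3 uncharacterized genes chosen after their values were seen. The rise of AT2G06950 was not seen with the 4 libraries of the first set (-0.15, edgeR adjusted p = 0.621), so it cannot be tied to the knockout. The other subunits did not pass: BADC2 had 0.29 (SE 0.25), BCCP1 -0.05 (SE 0.29), BCCP2 0.12 (SE 0.23), CAC2 0.12 (SE 0.23), CAC3 0.09 (SE 0.21) and the plastid-encoded accD -0.50 (SE 0.82), each with an adjusted p of 0.997, and the regulators CTI1 -0.01 (SE 0.22) and GLB1 0.18 (SE 0.28) did not either. All 13 storage protein genes were positive, with a median of 0.58, and 7 were higher adjusted over the list alone against 0 over all genes. Oil body genes had a median of 0.47 and 13 of 14 positive (5 higher adjusted over the list alone, 0 over all genes), and seed coat genes a median of -0.53 (6 lower adjusted over the list alone, 0 over all genes). Cell division genes had a median of -1.32, with 1 of 10 positive, photosynthesis genes -0.44, with 1 of 54 positive, and mitochondrion-encoded genes 0.63, with 33 of 39 positive, and 0 genes of these lists passed with edgeR, adjusted over all genes or over the list alone. Camera called 13 lists, these 6 among them, and none held with an estimated correlation (adjusted p = 0.27, 0.27 and 0.38 for storage, oil body and seed coat genes, and between 0.27 and 0.78 for the others). Fry called 0 lists (lowest adjusted p = 0.066, for storage proteins and for carboxylase and BADC genes). The mitochondrion-encoded share of counts was 0.0327% in AtWT replicate 1 and 0.175% and 0.151% in AtWT replicates 2 and 3. In AtBD it was 0.103% to 0.246%. The plastid-encoded share was 0.0121%, 0.110% and 0.123% in AtWT replicates 1 to 3, and 0.0537% to 0.142% in AtBD. The shifts of both organelle lists may thus rest on AtWT replicate 1. With the replicate block, camera's calls of the carboxylase and BADC list (adjusted p = 0.060) and of fatty acid synthesis (0.070) were lost. For the carboxylase and BADC list the median (0.04) and the mean (-1.28) differed in sign. The count was 77 with DESeq2, 26 with no filter on low counts and 288 with only the libraries compared. It was 7 without AtBD replicate 2, AtBD replicate 3 or AtWT replicate 1, and 6 without AtWT replicate 3, and of the 9 named genes BADC1, BADC3, AT1G72680 and FKF1 passed under all 14 alternatives.

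In the tr libraries the genotype contrast again held both targets. BADC3 fell by 8.28 (SE 0.51) and BADC1 by 4.76 (SE 0.31), each with an adjusted p of 6.06e-07, and AT1G72680 rose from 3.77 ± 1.04 to 51.4 ± 12.7 CPM (SD, n = 3 each). SERAT1;1 (AT5G56760), a serine acetyltransferase of cysteine synthesis, rose by 1.27 (SE 0.21). AGL87 (AT1G22590), a MADS-box factor, fell by 2.15 (SE 0.31) and AT4G27450, annotated as an aluminum induced protein, by 1.86 (SE 0.30). Photosynthesis genes had a median of -1.17 with 0 of 54 positive (0 lower over all genes and 1 adjusted over the list alone).

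Of the 19376 genes, 10 passed in AtBDtr against AtWTtr (3 higher, 7 lower), 5 of them shared with AtBD against AtWT: BADC1, BADC3, AT1G72680, AT2G06950 and AT5G35935. Chance gives fewer than 1 shared gene per direction. Outside the rule, AT2G41640 had -3.36 (SE 0.46) and the vegetative storage protein VSP1 -2.13 (SE 0.36), chosen after their values were seen. Camera called 6 lists lower (photosynthesis, carboxylase and BADC, cell division, hypoxia, ER protein folding, fatty acid synthesis), and none held with an estimated correlation (adjusted p = 0.53 for photosynthesis, cell division and ER protein folding, 0.34 for carboxylase and BADC, 0.12 for hypoxia and 0.91 for fatty acid synthesis). Fry called hypoxia (adjusted p = 0.0075) and carboxylase and BADC genes (0.013), both lower. The latter list holds the knocked-out genes. BADC2, BCCP1, BCCP2, CAC2, CAC3, CTI1 and GLB1 also had a lower mean CPM in AtBDtr than in AtWTtr, though none of them passed alone. The subunit accD, near the floor, did not. Fry's call of this list was lost with the replicate block (0.053). The groups did not overlap for 7.19% of genes, where chance gives 10%. With the replicate block the count was 7, and 2 named genes lost the call. The count was 21 with DESeq2 and 5 with only the libraries compared, and AGL87, AT4G27450 and SERAT1;1 each lost the call in that fit. Leaving out AtBDtr replicate 3 ended the call for all 3 (highest adjusted p over the alternatives 0.294 for AGL87). Leaving out AtBDtr replicate 1, AtBDtr replicate 2 or AtWTtr replicate 1 ended it for AT4G27450 and SERAT1;1, as did AtWTtr replicate 3 for AT4G27450 and AtWTtr replicate 2 for SERAT1;1 (highest adjusted p over the alternatives 0.831 and 0.809).

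The comparison of AtWTtr with AtWT asks which transcripts are over- or under-represented in the tr libraries. In wild type, most storage protein, oil body and late maturation genes were higher in AtWTtr. All 13 storage protein genes rose (13 adjusted over the list alone), with a median of 2.15 on the log2 scale: the 2S albumin SESA4 went from 22499 ± 6920 to 103095 ± 12713 CPM (SD, n = 3 each). Of 14 oil body genes 11 rose and 0 fell (12 and 1 adjusted over the list alone), with the oleosin OLEO1 at 2.58 (SE 0.27) and the caleosin CLO1 at 2.04 (SE 0.23). Of 21 late maturation and desiccation genes 17 rose (21 adjusted over the list alone), with a median of 2.92, among them the dormancy gene DOG1 at 2.46 (SE 0.23) and the peroxiredoxin PER1 at 2.12 (SE 0.29). The list of maturation regulators was split (8 higher and 8 lower of 21, median -0.83), and ABI3 (AT3G24650), 1 of its members, rose from 62.6 ± 15.2 to 291 ± 39.7 CPM.

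Genes of maternal tissues, of dividing cells and of the organelles fell in AtWTtr against AtWT. Of 15 seed coat genes 13 fell and 0 rose (13 and 0 adjusted over the list alone), with a median of -3.25: the laccase TT10 went from 549 ± 127 to 21.7 ± 7.03 CPM and the mucilage gene MUM2 from 44.9 ± 5.50 to 2.85 ± 0.810. Of 5 silique wall genes 4 fell (5 adjusted over the list alone), among them SHP2 at -5.10 (SE 0.64). Of 10 cell division genes 7 fell (7 adjusted over the list alone), among them the cytokinesis syntaxin KNOLLE at -4.02 (SE 0.67). Of 5 endosperm genes 3 fell and 1 rose (3 and 1 adjusted over the list alone): ALE1 was at -7.99 (SE 0.82), ZOU at -3.55 (SE 0.66) and SUC5 at -2.79 (SE 0.61), and EPR1 at 1.94 (SE 0.32). Of 74 plastid-encoded genes 64 fell (71 adjusted over the list alone), and of 39 mitochondrion-encoded genes 21 (29 adjusted over the list alone). With genes without a count in AtWTtr at their bound, the medians of these 2 lists were -4.48 and -2.98. The plastid-encoded carboxylase subunit accD had 4.08 ± 3.88 CPM in AtWT and no count in AtWTtr, at least 53.1-fold lower over the floor (25.7-fold without AtWT replicate 2 and 86.2-fold without AtWT replicate 1). Of 10 carboxylase and BADC genes 2 rose and 1 fell (2 and 1 adjusted over the list alone), and the median (0.24) and the mean (-0.71) differed in sign. The 2 that rose, BCCP2 at 0.77 (SE 0.23) and BADC2 at 0.69 (SE 0.25), missed the threshold with the replicate block, with only the libraries compared, and without AtWT replicate 3, AtWTtr replicate 1 or AtWTtr replicate 3 (highest adjusted p = 0.0839 and 0.153). BADC2 also missed it with RLE scaling and without AtWT replicate 2.

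**Figure D2:**
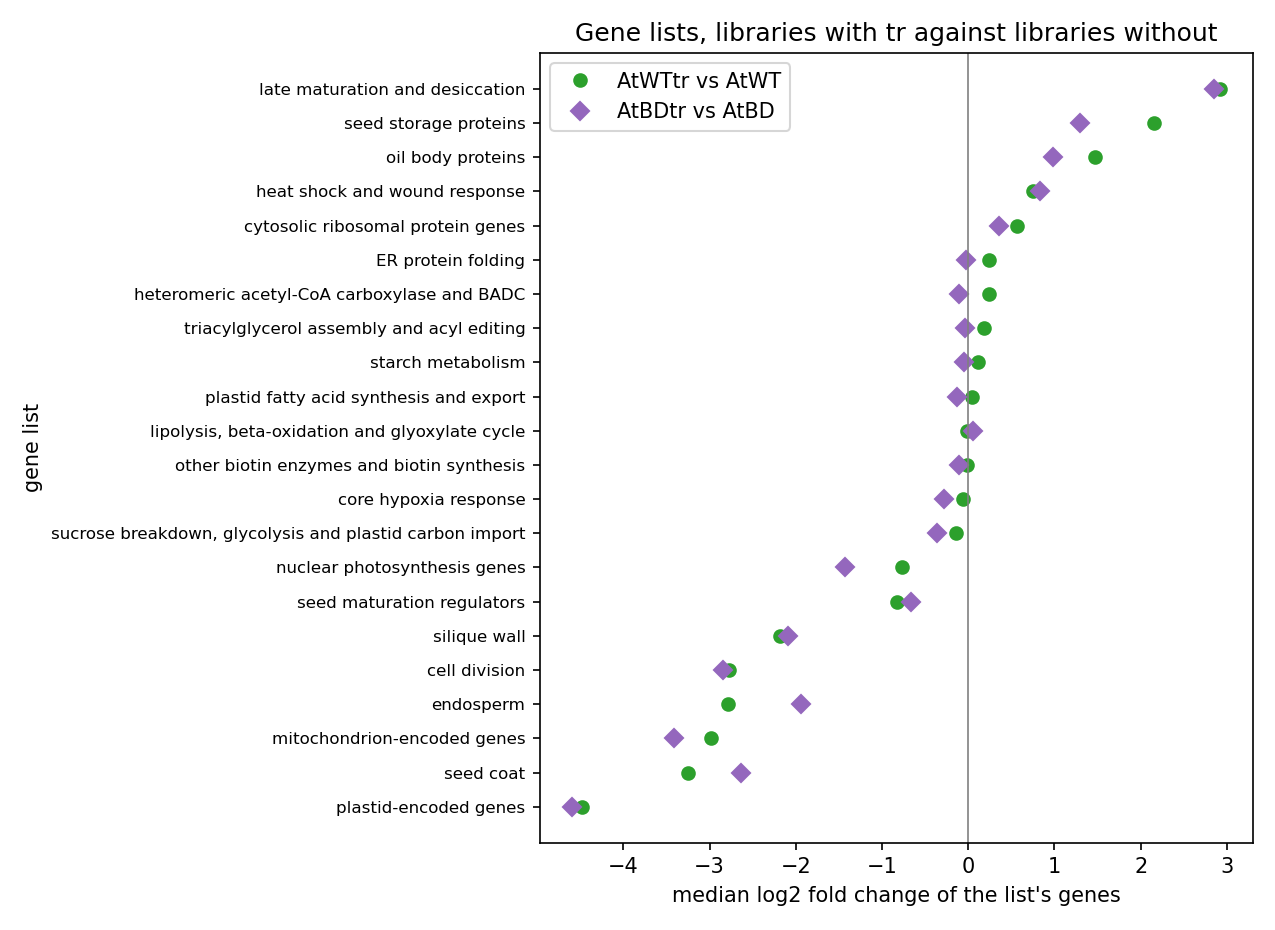
Median log2 fold change of each gene list in the tr libraries against the others, in wild type (circles) and in the double mutant (diamonds), with genes without a count at their bound. Late maturation genes lie at 2.92 and 2.85, seed coat genes at -3.25 and -2.64.

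Metabolic lists moved in both directions in AtWTtr against AtWT. Plastid fatty acid synthesis had 7 higher and 1 lower of 32 (7 and 1 adjusted over the list alone), with the acyl carrier protein ACP1 at 1.38 (SE 0.22), the exporter FAX2 at 1.37 (SE 0.21) and FAB2 at 1.13 (SE 0.19). Triacylglycerol assembly had 3 higher and 2 lower of 17 (3 and 1), with the linoleate desaturase FAD3 from 733 ± 50.1 to 1685 ± 285 CPM and the acyltransferase DGAT1 at 0.96 (SE 0.16) against AAPT2 at -2.42 (SE 0.22). Starch metabolism had 9 higher and 5 lower of 28, sucrose breakdown and glycolysis 2 and 5 of 28, lipolysis with the glyoxylate cycle 3 and 5 of 22 and maturation regulators 8 and 8. Adjusted over the list alone these were 10 and 5, 2 and 5, 3 and 6, and 8 and 11. The sucrose synthases SUS1 and SUS3 were at -2.59 (SE 0.28) and 2.33 (SE 0.38). Hypoxia genes had 1 higher and 3 lower of 11 (1 and 3), heat shock and wounding 4 and 2 of 10 (6 and 2), ER protein folding 2 and 0 of 8 (2 and 0), and other biotin enzymes 0 of 8 (0), where the adjusted values over the list alone stand in brackets. The wound-response genes LOX2 and VSP2 were at -3.21 (SE 0.24) and -3.18 (SE 0.31). Nuclear photosynthesis genes had 10 lower and 0 higher of 54 (6 and 0 adjusted over the list alone), among them the rubisco activase RCA at -2.45 (SE 0.25). Of 192 cytosolic ribosomal protein genes 85 rose and 5 fell (103 and 5 adjusted over the list alone), with a median of 0.56.

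RPL18 (AT3G05590), of the gene family of the tagged transgene, rose from 1038 ± 93.4 CPM in AtWT to 20400 ± 5426 in AtWTtr, a log2 change of 4.30 (SE 0.25, adjusted p = 2.17e-08). Its paralog AT5G27850 went from 232 ± 88.0 to 360 ± 65.9 CPM (0.63, SE 0.27, adjusted p = 0.0778; past the threshold without AtWT replicate 2), and the third RPL18 gene, AT2G47570, had no count in the second set. Other genes among the largest rises were FTIP1 (AT5G06850), at 5.02 (SE 0.38), the ENTH-domain gene AT5G35200, from 13.9 ± 0.606 to 279 ± 26.0 CPM, and EM1 (AT3G51810), an embryo LEA protein, at 4.08 (SE 0.86). Among the largest falls were the dirigent-like AT4G11180, at -7.18 (SE 1.16), the arabinogalactan protein FLA5, at -7.06 (SE 1.05), and the fatty acid elongase KCS19, at -6.34 (SE 0.87).

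**Figure D3:**
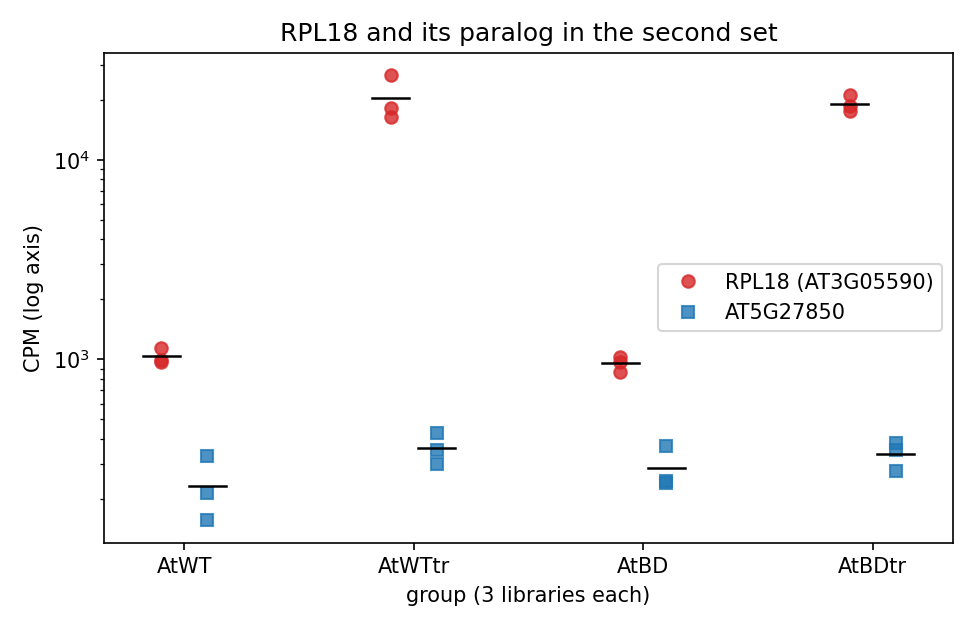
CPM of RPL18 and its paralog AT5G27850 in the 12 libraries of the second set (log axis; points are libraries, bars are means of 3). RPL18 averages 20400 CPM in AtWTtr and 19099 in AtBDtr, against 1038 in AtWT and 955 in AtBD.

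In all, 6616 of 19376 genes passed in AtWTtr against AtWT, 2943 higher and 3673 lower, and 48.6% of genes did not overlap, where chance gives 10%. Camera called 10 lists: storage, oil body, late maturation and ribosomal protein genes higher, and plastid-encoded, mitochondrion-encoded, seed coat, silique wall, cell division and photosynthesis genes lower. None held with an estimated correlation (adjusted p = 0.063 for storage, seed coat, silique wall and mitochondrion-encoded genes, and between 0.20 and 0.90 for the other 6). Fry called 11 lists: storage (adjusted p = 9.1e-06), oil body (0.00014), late maturation (0.0032) and ribosomal protein genes (0.02) higher, and seed coat (1.7e-06), silique wall (6.8e-06), mitochondrion-encoded (2.2e-05), plastid-encoded (0.00071), endosperm (0.003), hypoxia (0.0059) and cell division genes (0.013) lower, but not photosynthesis (0.18). With the replicate block, fry's call of ribosomal protein genes was lost (0.13). Storage protein genes took 23.0% ± 2.33 of all counts in AtWT and 46.9% ± 3.86 in AtWTtr (SD, n = 3 each). The mix of transcripts thus differs between the 2 groups. TMM scaling, which the CPM and fold changes carry, is meant to offset this, and the median log2 change of all genes was -0.04.

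The same contrast in the mutant gave a like pattern. AtBDtr against AtBD raised 11 of 13 storage protein genes (12 adjusted over the list alone; mean 1.26), 10 of 14 oil body genes (12 adjusted over the list alone, 1 fell in both counts; median 0.99) and 20 of 21 late maturation genes (21; median 2.85). It lowered 13 of 15 seed coat genes (13; median -2.64), 5 of 5 silique wall genes (5; with counts of 1 strand SHP1 turned from -1.58 to 0.28), 4 of 10 cell division genes (7), 63 of 74 plastid-encoded genes (71), 25 of 39 mitochondrion-encoded genes (34) and 31 of 54 photosynthesis genes (40), where the brackets hold the counts adjusted over the list alone. Cruciferin CRU3 rose from 31228 ± 6375 to 105930 ± 28606 CPM (SD, n = 3 each), TT10 fell from 295 ± 92.2 to 17.8 ± 4.62 and RPL18 rose from 955 ± 84.6 to 19099 ± 1776. Maturation regulators had 8 higher and 7 lower of 21 (8 and 10; median -0.66), with ABI3 at 2.02 (SE 0.21), and heat shock and wound genes 5 higher and 2 lower of 10 (6 and 2; median 0.83), with LOX2 among the lower ones at -3.53 (SE 0.24). The subunit accD had between 52 and 98 counts in the AtBD libraries, 4 in AtBDtr replicate 2 and none in AtBDtr replicates 1 and 3, so that its fold change is not given.

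Here 5753 genes passed, 2490 higher and 3263 lower, and 47.0% of genes did not overlap, where chance gives 10%. Camera called the same 10 lists in the same directions as in wild type, and none held with an estimated correlation (adjusted p = 0.13 for storage proteins, 0.069 for seed coat, silique wall and mitochondrion-encoded genes, and between 0.28 and 0.70 for the other 6). Fry also called 11 lists, 10 of those it called in wild type in the same directions (adjusted p between 1.1e-05 and 0.0076) and photosynthesis lower (0.02), but not ribosomal protein genes (0.11). With the replicate block, fry's calls of endosperm (0.051) and photosynthesis genes (0.081) were lost. Across the 19376 genes the log2 changes of the 2 genotypes had Pearson's r = 0.818 and Spearman's rho = 0.832, where genes are not independent replicates. Both contrasts called 1899 genes higher (378 by chance), 2620 lower (619 by chance) and 0 in opposite directions.

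The interaction asks whether the ratio of tr to other libraries differs between genotypes, the comparison that the study describes as translation efficiency. RPL18 had a difference of 0.02 (SE 0.31), BADC2 -0.45 (SE 0.35), BCCP2 -0.52 (SE 0.33) and CAC3 -0.24 (SE 0.30) on the log2 scale. Storage protein genes had a median difference of -0.64, with 0 of 13 positive, photosynthesis genes -0.67, with 2 of 54 positive, oil body genes -0.52, with 1 of 14 positive, and seed coat genes 0.61, with 13 of 15 positive. Camera called 7 lists, these 4 among them, and none held with an estimated correlation (adjusted p = 0.55 for storage proteins and seed coat, 0.71 for photosynthesis, oil body, fatty acid synthesis and mitochondrion-encoded genes, and 0.77 for ribosomal protein genes). Fry called 0 lists (lowest adjusted p = 0.30). Storage, oil body and seed coat genes had medians of the opposite sign in AtBD against AtWT. Camera called none of these lists in AtBDtr against AtWTtr. A genotype difference in the libraries without tr alone could thus give such shifts of the ratio.

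No gene passed in the interaction with edgeR among 19376, where 790 had an unadjusted p under 0.05. DESeq2 gave 4 (962 unadjusted): AT1G28710 and AT4G14330 with a higher ratio in the mutant, and AT1G56300 and AT3G57965 with a lower one, each with an adjusted p of 0.0494, chosen after their values were seen. A z-score of at least 2, the kind of criterion the study names, marked 1276 genes (894 higher, 382 lower) and carries no error rate. The replicate block called 1 gene, LCR67, with an adjusted p of 0.0288.

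The genotype changes of the 2 sets were compared over genes and lists. Across 15493 genes tested in both, the log2 changes of badc-tdna13 against COL0 and of AtBD against AtWT had Pearson's r = 0.0045 and Spearman's rho = -0.023, with the same sign in 47.7%. With the 2 identical libraries left out, r was 0.017 and rho -0.023, and of the genes past the threshold in both, 2 were lower in both (0.231 by chance), 0 were higher in both and 0 opposite. These were BADC3 and AT5G35935, the latter at -1.64 in the first set (adjusted p = 0.0202). IAA32 had -1.14 there (adjusted p = 0.0595) against 1.74 in AtBD. In the fit of only the AtBD and AtWT libraries, GPT2 was called higher in AtBD, opposite to its fall in the first set. ICL and LHCB2.2 were called in the same direction as in the first set. Against AtBDtr and AtWTtr, the 4 libraries of the first set gave r = 0.098 and rho = 0.114, with 2 genes lower in both (0.347 by chance), 0 higher in both and 1 opposite (AT2G41640). By camera, 4 lists moved alike with the 4 libraries of the first set and in AtBD: photosynthesis (adjusted p = 1.7e-06 and 8.9e-05) and cell division genes (0.0052 and 0.0059) lower, and late maturation (5.3e-08 and 0.034) and plastid-encoded genes (0.0041 and 0.0017) higher. Mitochondrion-encoded genes were called higher in AtBD (1.2e-05) and with all 6 libraries of the first set (0.019), but not with 4 (0.12). The calls of both organelle lists in AtBD may rest on AtWT replicate 1, which had the lowest organelle shares of the AtWT and AtBD libraries. The carboxylase and BADC list was called lower in both sets (0.0058 with 4 libraries, and 0.042), but in AtBD its median was 0.04, with 5 of 10 members positive, and the 2 genes past the threshold were the knocked-out ones. Fatty acid synthesis, starch and ribosomal protein genes were called lower in the first set (1.4e-06, 0.016 and 0.0058) and higher in AtBD (0.050, 5.3e-05 and 7.8e-06). No call held with an estimated correlation.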

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

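The split counts, the tests of duplicate entry, of a mutant library, of organelle and promoter-cell RNA, of storage protein counts and of RPL18 were chosen after the results were seen. The Poisson pairs were chosen before their results were seen.

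Between the genotypes, the difference of the tr effect (AtBDtr against AtBD less AtWTtr against AtWT) shifted in 7 gene lists by camera with a preset correlation, the test of the difference itself. The median log2 difference was -0.64 for storage proteins (camera adjusted p = 1.8e-06), -0.67 for nuclear photosynthesis genes (7e-08), -0.52 for oil body proteins (0.00046), -0.29 for plastid fatty acid synthesis (0.00097), -0.19 for ribosomal protein genes (3.5e-05), -0.78 for mitochondrion-encoded genes (0.016) and 0.61 for seed coat genes (0.0012). With an estimated correlation none passed (adjusted p = 0.55 for storage proteins and seed coat, 0.77 for ribosomal protein genes, 0.71 for the other 4). The medians of storage, oil body, seed coat and mitochondrion-encoded genes had the opposite sign in AtBD against AtWT. Camera called none of these lists in AtBDtr against AtWTtr, so a genotype difference in the libraries without tr alone could give their shifts. Among the libraries without tr, AtWT replicate 1 had the lowest mitochondrion-encoded share of counts (0.0327%, against 0.103% to 0.246% in the others). No biological explanation of these 7 shifts was tested.

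Col-0 replicate 2 and tDNA replicate 2 held identical fragments at 100% of 17412 loci with the Cuffdiff status OK. With loci of any status, 1 differed. Pairs of libraries drawn with Poisson noise around the common value shared at most 2.46% of loci (100 pairs), which argues against separate libraries that match by sampling. A single library entered under both groups is a candidate explanation. In the shared library, BADC3 stood at 65.3 CPM, against 6.98 and 3.36 in tDNA replicates 0 and 1 and 89.6 and 92.4 in Col-0 replicates 0 and 1. The BADC1 locus stood at 101.7 CPM, against 33.7 and 36.6, and 100.2 and 100.5. Both genes lay above the other mutant libraries by more than their range, which argues against a library of the double mutant entered under both groups. BADC2 in the shared library lay nearer to the mutant. It stood at 114 CPM, against 119 and 108 in tDNA replicates 0 and 1 and 217 and 223 in Col-0 replicates 0 and 1. The log2 correlation of the shared library across loci favoured neither group. It was 0.942 with tDNA replicate 1, 0.850 with tDNA replicate 0, and 0.905 and 0.887 with Col-0 replicates 0 and 1. A mixture of both genotypes was not tested, so the origin of this library stays open. No library was moved to another group.

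Seed coat, silique wall and organelle-encoded genes were lower and storage protein genes higher in the tr libraries. In unscaled counts, the share taken by storage protein genes would shift every other gene alike, by -0.54 log2 in wild type and -0.36 in the mutant. Between any 2 libraries this shift would be at most -0.70 and -0.50. TMM scaling is meant to remove such a shift, and the median log2 change of all genes was -0.04 and -0.03. The highest median of the 4 lowered lists was -2.18 and -2.09, and the upper quartile of seed coat genes -2.03 and -1.43. These TMM-scaled falls exceed even the whole unscaled shift, which argues against a few genes taking most of the counts as their cause. RNA of the cells that use the storage protein promoter may explain the loss of seed coat, endosperm and silique wall transcripts, of which 20 were lower and 1 higher past the threshold in wild type. The test could only count against this explanation, so it stays open. Loss of organelle transcripts with cytosolic ribosomes also stays open. In wild type the mitochondrion-encoded median of -2.98, with genes without counts at their bound, was only an upper limit. The test could thus not tell whether it lay below the lowest nuclear list, seed coat genes at -3.25. The plastid-encoded median (-4.48) did. In the mutant, both organelle medians at their bounds (-4.59 and -3.42) lay below the lowest nuclear list (-2.84). A nuclear list may also be low for another reason, so this ranking cannot decide. Biological differences between the plants that gave tr and other libraries were not tested.

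RPL18 (AT3G05590) rose in the tr libraries of both genotypes. Of 191 other ribosomal protein genes, 0 rose as much by edgeR's fold (the next highest log2 change was 1.46 in wild type and 1.3 in the mutant). The list rose in general, but with a median of only 0.56 and 0.36. These values argue against a general rise of ribosomal protein genes as the whole cause of the rise of RPL18. Counting of transgene transcripts at AT3G05590 is a candidate explanation. It would give a like rise in both genotypes and no such rise of the paralog AT5G27850, which moved by 0.63. The values met both, but the test could only count against this explanation, and reads of the transgene were not told apart, so it stays open. RPL18 also ranked 1 among ribosomal protein genes in the libraries without tr (996 CPM, next 437). The interaction for RPL18 was 0.02 (SE 0.31).

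The 6 libraries of a comparison make 10 splits, too few for a share under 0.05. AtBD against AtWT gave 12 genes and the highest other split 0. AtWTtr against AtWT gave 6616 and AtBDtr against AtBD 5753, with 0 for the highest other split of each. AtBDtr against AtWTtr gave 10, and 2 of the 10 splits gave as many, the highest other 749 (AtBDtr replicates 1 and 2 with AtWTtr replicate 2 against the rest), which points to a structure of these samples beyond genotype. The first set gave 0, so all 10 splits gave as many, which says nothing about chance. The highest other, 3958, had the identical libraries in 1 group, whose spread is lowered by the copy. For the interaction, 0 genes passed with edgeR (790 at an unadjusted p under 0.05; DESeq2 4), and 50 of 50 drawn splits of 200 gave as many, as any split must against a count of 0, with 10 for the highest other, so these splits do not test chance.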

How the results depend on the processing

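Leaving out the identical libraries, every alternative for the 4 libraries that remain, counts of 1 strand and the correlations without single libraries were chosen after the data were seen. The count for badc-tdna13 against COL0 was 0 under every other alternative (edgeR; DESeq2 0, 974 and 1093 at an unadjusted p under 0.05) and 2092 with the identical libraries left out, which was then 1176 with a fold minimum, 765 with log2(FPKM + 1), 729 with log2(FPKM + 0.1) and 2 to 7554 without single libraries. Where both identical libraries were kept, a count of 0 does not argue against a genotype difference. AtBD against AtWT gave 77 with DESeq2, 26 with no filter on low counts, 288 with only the libraries compared and 6 to 8 without single libraries. AtBDtr against AtWTtr gave 21 with DESeq2 and 5 with only the libraries compared. The interaction gave 4 with DESeq2, 1 with the replicate block and 1276 with a z-score of at least 2. The causes were not tested.

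AtWTtr against AtWT stayed between 4682 and 7298 genes and AtBDtr against AtBD between 4037 and 6570 under all alternatives. The median log2 change of all genes in AtWTtr against AtWT was -0.04, -0.09 with RLE scaling and -0.19 with no filter on low counts. Of 57 list calls by camera, 0 remained with an estimated correlation. The correlation of the genotype comparisons was 0.0045, -0.020 for genes with a mean log2 CPM of at least 2 and -0.031 to 0.049 without single libraries. SHP1 in AtBDtr against AtBD changed sign, from -1.58 to 0.28 with counts of 1 strand; the cause was not tested. Among checks of named genes, 48 of 1459 fell below the threshold in AtBDtr against AtBD, 35 of 1489 in AtWTtr against AtWT, 30 of 265 in AtBD against AtWT, 16 of 222 in AtBDtr against AtWTtr and 195 of 835 with the 4 libraries of the first set. At these depths and 3 libraries per group, simulated 2-fold changes were recovered in at most 21.6% of genes in the second set.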

Other observations

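A fit of only the 6 AtBD and AtWT libraries gave 288 genes (77 higher, 211 lower), among them the 12 of the fit with all 12 libraries. Which of these genes are named here was chosen after their values were seen. Lower in AtBD were 5 of 10 cell division genes (KNOLLE, CDKB2;2, CDKB2;1, CDC20.1, CYCB1;2), 7 of 54 photosynthesis genes, 3 of 15 seed coat genes (MYB61, BAN, MUM2), 2 of 5 endosperm genes (ALE1, SUC5) and LEC1. Higher were DOG1, ICL, PHS1, GPT2 and FAD3. In that fit ELF4 (AT2G40080) was at 1.71 (SE 0.30) and JMJD5 (AT3G20810) at 1.35 (SE 0.29). LSU1 (AT3G49580), a gene of the low-sulfur response, fell by 3.08 (SE 0.44), and carbonic anhydrase CA1 (AT3G01500) by 2.49 (SE 0.26). With all 12 libraries their adjusted p was 0.381, 0.686, 0.425 and 0.398. In AtBDtr against AtWTtr ELF4 had 0.74 and LSU1 -0.18.

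Storage protein genes took 31.0% ± 2.01 of counts in AtBD and 23.0% ± 2.33 in AtWT (SD, n = 3 each). Plastid-encoded genes took 0.0840% and 0.0816% there, and 0.00181% in AtBDtr and 0.000811% in AtWTtr.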
